A study of Xenopus laevis with 10 samples.

How the data were processed

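The series holds 10 one-colour Affymetrix expression arrays of Xenopus laevis animal cap explants. Each array carries total RNA of one pool of explants. Groups were taken from the labels: 5 samples were injected with 400 pg of Six1 mRNA into each of the 2 cells, and 5 were uninjected. Caps of the Six1 samples were removed at stages 8 to 9, and both groups were cultured in 200 ng/ml Noggin and collected at stages 15 to 16. The labels state that the control pools came from eggs of 1 or 2 females and were siblings of the Six1 sample with the same number. They do not say that different numbers came from different clutches, so p-values rest on the spread between these pools. The source label names a whole animal and a cochlea, while the descriptions name animal caps. The descriptions were followed. One Six1 sample of 40 explants has a title that names a biotin-labelled cDNA and no number. It was placed in the Six1 group by its description and was never paired.

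The deposited values are intensity values on a linear scale, 1 per probe set and array, and the authors' summary and scaling algorithm is not given in the sources used here. In the deposited table each array has the same mean, 150.02, after the highest and lowest 2% of values are removed, so the arrays had been scaled to a common trimmed mean. The table used here has no detection calls. Scaling to a common mean leaves differences in the median, which ran over 0.18 on the log2 scale between arrays, and these can tilt the balance of higher and lower calls.

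Of 15611 probe sets, 120 AFFX controls were left out of the tests. Of the other 15491, 9304 have 1 gene symbol in the platform annotation, 195 have several and 5992 have none. Entrez identifiers matched 9227 of the 9304 to the gene table of assembly Xenopus_laevis_v10.1, which was used for names only, and 2 symbols were updated. A symbol ending in .L or .S is one of the homeologous copies of a gene in this allotetraploid species, and near-identical copies can share probes, above all in probe sets whose identifiers end in _s_at, _x_at or _a_at. Those used for sox2.L, tuba1cl.3.L and myod1.S are of this kind. 0 probe sets have the symbol six1.

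Values were transformed to log2(signal + 16). No further normalization was applied, since the array medians lay within the tolerance of 0.2 set for this. The dimmest 30% of probe sets by mean over the 10 arrays were left out, and 10843 were tested. Fold changes are on the log2(signal + 16) scale, which understates the change of dim probe sets. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all probe sets tested, threshold 0.05), on all 10 arrays and without a block. The alternative with the sibling pair as a block used the 8 arrays numbered 2 to 5. In limma the variance of a probe set is drawn towards that of all probe sets, with 13.0 prior degrees of freedom in the paired fit. The printed SEs include this, so for variable genes they are smaller than the gene's own spread would give. For prickle1.S the paired SE was 0.24. Its 4 pair differences had an SD of 0.83, which must be divided by the square root of 4 before it is compared with that SE. Same-numbered samples deviated from their group means together (r over probe sets 0.54, 0.48, 0.39 and 0.44 for pairs 2 to 5). Each of the 4 numbered Six1 arrays correlated best with its own sibling, and their highest value with another control was 0.20. Six1 6, which has no sibling here, reached 0.21 with control 2. Since the labels name siblings, results of the paired fit are printed beside the others. Exact permutation tests were used for values compared per array. The number of arrays limits the precision.

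The 22 gene lists, the rule for named genes, the tests and their alternatives were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists) on 1 probe set per gene, that of the highest mean. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera takes its degrees of freedom from the arrays, so it has little power here. A call lost with it need not mean that the members are correlated. Among the variance alternatives camera took the trend and the array weights, but not the robust estimation. List members were matched by symbol without the copy suffix or by synonym, and 2 synonym matches to unrelated genes (srsf5a.L and boc.L) were removed. Named genes were six1, the 12 largest rises and 12 largest falls among named genes past the threshold (or the 5 of smallest p in a direction where fewer than 5 passed), each list's passing members with up to 4 of smallest p, and the smallest-p member of a list where none passed. The use of this rule on the sibling pairs, where list members were named only if they passed or had the smallest p of a list with none, was decided after seeing the data. So were the scaling, pseudocount, filter, variance and leave-out alternatives of the paired fit. The probe set without a gene name that differed most and LOC100036828 fall outside the rule.

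Alternatives were quantile normalization, median centring, a pseudocount of 1 or 64, no filter or removal of the dimmest 50%, a variance trend with robust estimation, array weights, the pair as a random block (duplicateCorrelation, statmod 1.5.0), the 8 numbered arrays without a block, a threshold of 0.10, a minimum of 1.5-fold, 1 probe set per named gene, the mean of a gene's probe sets, and each array or pair left out in turn. The scripts were tested on simulated data over 10843 probe sets. On all arrays they recovered 2.94% of changes of 0.5, 62.1% of changes of 1 and 93.9% of changes of 2 on the log2 scale, with 1 false call among 106. In the paired fit they recovered 2.94%, 57.6% and 98.5%, with 3 false calls among 108. Simulated values were independent and normal, and both fits made similar numbers of calls, unlike on the real arrays. These shares check the scripts and do not give the power on the real data. There, on all arrays, a difference of 1.78 (prickle1.S) did not pass (limma adjusted p = 0.18).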

Results

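Animal caps, the prospective ectoderm at the top of the Xenopus laevis blastula, were profiled on 10 one-colour Affymetrix arrays after culture in Noggin, a secreted BMP antagonist that turns this tissue neural. In 5 samples, mRNA of Six1, a homeobox transcription factor of the preplacodal ectoderm, had been injected into both blastomeres of 2-cell embryos at 400 pg per cell. The other 5 samples were uninjected sibling explants. No group received a control mRNA, so an effect of the injection itself cannot be told apart from an effect of Six1. Each sample was total RNA of a pool of explants collected at neural fold stages (15 to 16), with 40 to 140 explants per Six1 pool and 97 to 130 per control pool. Controls 2 to 5 were siblings of the Six1 samples with the same number, which gave 4 sibling pairs. Control 1 and the Six1 sample without a number in its title, called Six1 6 here, had no partner. The median signal of an array was 38.6 ± 1.75 (SD, n = 5) in controls and 42.1 ± 1.34 (SD, n = 5) in Six1 samples. This shift of 0.09 on the log2 scale was larger than the spread between replicates (exact two-sided permutation test, p = 0.0159). That test ignores the sibling pairs. The Six1 array had the higher median in each of the 4 pairs, but exchanges within 4 pairs are too few for a p under 0.05. Control 4 stood apart in RNA quality, with a beta-actin 3'/5' signal ratio of 5.104 against 0.478 to 1.16 in the other controls and 0.677 to 1.42 in Six1 samples.

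The comparison asked which genes differed between Noggin-treated caps with and without injected Six1. No probe set carried the symbol six1 in the annotation used here, so the injected gene could not be read by name. The largest difference on the arrays belonged to a probe set without a gene name, singled out after its values were seen. Its signal was 2742 ± 1465 (SD, n = 5) in Six1 samples and 4.11 ± 3.58 (SD, n = 5) in controls, with no overlap (1171 to 4858 against 0.683 to 8.35). The log2 difference was 6.94 (SE 0.31, limma adjusted p = 8.71e-09 over all probe sets tested). Over 21 alternative settings it ran from 5.19 to 9.24, and the call was kept in 21. With so low a control signal, the size of the difference depends on the pseudocount, which the SE does not cover.

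Across all 10 arrays, 3 named genes rose with Six1. zic2.L, a zinc-finger transcription factor of the neural plate and its border, rose 3.62-fold (log2 difference 1.85, SE 0.27, adjusted p = 0.025), from a signal of 76.9 ± 38.5 to 321 ± 132 (SD, n = 5 each). krt18.1.S, a type I keratin, rose 2.80-fold (log2 1.48, SE 0.23, adjusted p = 0.031) and aplnr.L, the apelin receptor, rose 2.24-fold (log2 1.16, SE 0.17, adjusted p = 0.025). The other copy of the receptor gene, aplnr.S, did not pass (log2 0.28, adjusted p = 0.81, and in the sibling pairs 0.23 and 0.61). A probe set with the placeholder symbol LOC100036828 fell 2.80-fold (log2 -1.49, SE 0.23, adjusted p = 0.031). With the unnamed probe set, 4 probe sets were higher and 1 was lower among 10843 tested by limma at an adjusted p of 0.05. At an unadjusted p of 0.05 the counts were 561 and 268. The rule for named genes took the 5 of smallest p in each direction, and the remaining 2 higher and all 5 lower did not pass. foxi1.L, a forkhead factor of the non-neural ectoderm, differed by 1.07 on the log2 scale (adjusted p = 0.064) and zic2.S by 1.32 (0.11). Among the lower genes, gata6.L differed by -1.02 (0.19). Adjusted p was 0.29 or higher for val.L (-1.15), rab25.L (-1.02), ccno.L (-0.96) and cxcr4.S (-0.54). The calls of zic2.L, krt18.1.S, aplnr.L and LOC100036828 lay close to the threshold: each was lost when control 2, control 5, Six1 5 or Six1 6 was left out, or with a pseudocount of 1, and those of zic2.L and LOC100036828 also with 64. krt18.1.S and LOC100036828 were also lost after quantile normalization or without Six1 2 or 3, zic2.L without Six1 3, control 3 or control 4, aplnr.L without control 4, and LOC100036828 without control 4 or Six1 4. On the 8 numbered arrays without a block krt18.1.S, aplnr.L and LOC100036828 were lost (adjusted p 0.052 to 0.18 over these settings).

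Within the 4 sibling pairs, a wide set of genes changed: 221 probe sets were higher and 159 lower with Six1 in limma with the pair as a block. These included the 5 found on all arrays. The difference over all arrays had the same sign for 380 of the 380, but it draws on the same paired arrays, so this is no independent check. The largest rises among named genes were those of prickle1.S, a planar cell polarity gene (4.54-fold, log2 2.18, SE 0.24, adjusted p = 1.8e-04), and zic2.L (4.43-fold, log2 2.15, SE 0.18, adjusted p = 1.33e-05). The prickle1.L copy rose 2.77-fold and zic2.S 2.75-fold, although a dimmer second probe set of zic2.S did not pass (log2 0.83, adjusted p = 0.057). mmp14.L, a membrane-anchored matrix metalloproteinase, rose 3.48-fold. sesn1.L, a sestrin induced by p53, rose 3.18-fold, and ackr3.L, an atypical receptor for the chemokine CXCL12, rose 3.02-fold. krt18.1.S rose 2.87-fold, chrng.L, the embryonic acetylcholine receptor subunit, 2.84-fold, ambp.L 2.81-fold and sfrp2.S, a secreted Frizzled-related protein, 2.75-fold. Each of these was higher with Six1 in 4 of 4 pairs. satpb.L rose 2.57-fold and was higher in 3 of 4. A second probe set of ambp.L did not follow (log2 -0.14, adjusted p = 0.74). Without the block, on all arrays, zic2.L and krt18.1.S passed as above. The other rises did not, with limma adjusted p from 0.11 (zic2.S) to 0.70 (satpb.L). Of the unpaired arrays, Six1 6 was below control 1 for ackr3.L (log2 signal 6.94 against 7.23) and above it for the others, by little for ambp.L and satpb.L.

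The largest falls within the sibling pairs were those of val.L (2.82-fold) and tuba1cl.3.L, an alpha-tubulin (2.81-fold), both with a log2 difference of -1.49. elovl2.L, a fatty acid elongase, fell 2.71-fold. rab25.L, a small GTPase of epithelial apical recycling, fell 2.56-fold. Both copies of the receptor tyrosine kinase gene kit fell, kit.S 2.51-fold and kit.L 2.27-fold, although a dimmer second probe set of kit.S did not pass (log2 -0.32, adjusted p = 0.33). agr2.S, a secretory pathway protein of the cement gland and mucous cells, fell 2.47-fold. cmahp.L fell 2.31-fold, and ccno.L, the cyclin needed to make the centrioles of multiciliated cells, fell 2.29-fold (log2 -1.19, SE 0.16, adjusted p = 0.0011). rabl2b.S fell 2.26-fold, itln1.L, an intelectin secreted by the embryonic epidermis, 2.23-fold and hal.1.L, histidine ammonia-lyase, 2.21-fold. Each of the 12 was lower with Six1 in 4 of 4 pairs. On all arrays without the block none of the 12 passed, with limma adjusted p from 0.29 (val.L) to 0.82 (itln1.L). Of the unpaired arrays, Six1 6 was above control 1 for val.L, elovl2.L, rab25.L, kit.S and cmahp.L, and below it for the others.

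The split between higher and lower calls depended on the scaling of the arrays, whose medians differed between the groups. Of the 380 calls 58.2% were higher. Quantile normalization gave 111 higher and 172 lower, and centring each array on its median gave 104 higher and 239 lower. The 24 named genes above kept their calls under both scalings. Without pair 3 the counts were 52 and 35, without pair 4, which holds the control with the high 3'/5' ratio, 97 and 108, and without pair 5 they were 84 and 60. Without pair 3 satpb.L and kit.L lost their calls, and without pair 4 chrng.L and satpb.L did. With a pseudocount of 1, 10 of the 24 kept theirs, among them zic2.L, prickle1.S, mmp14.L and ccno.L.

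**Figure D1:**
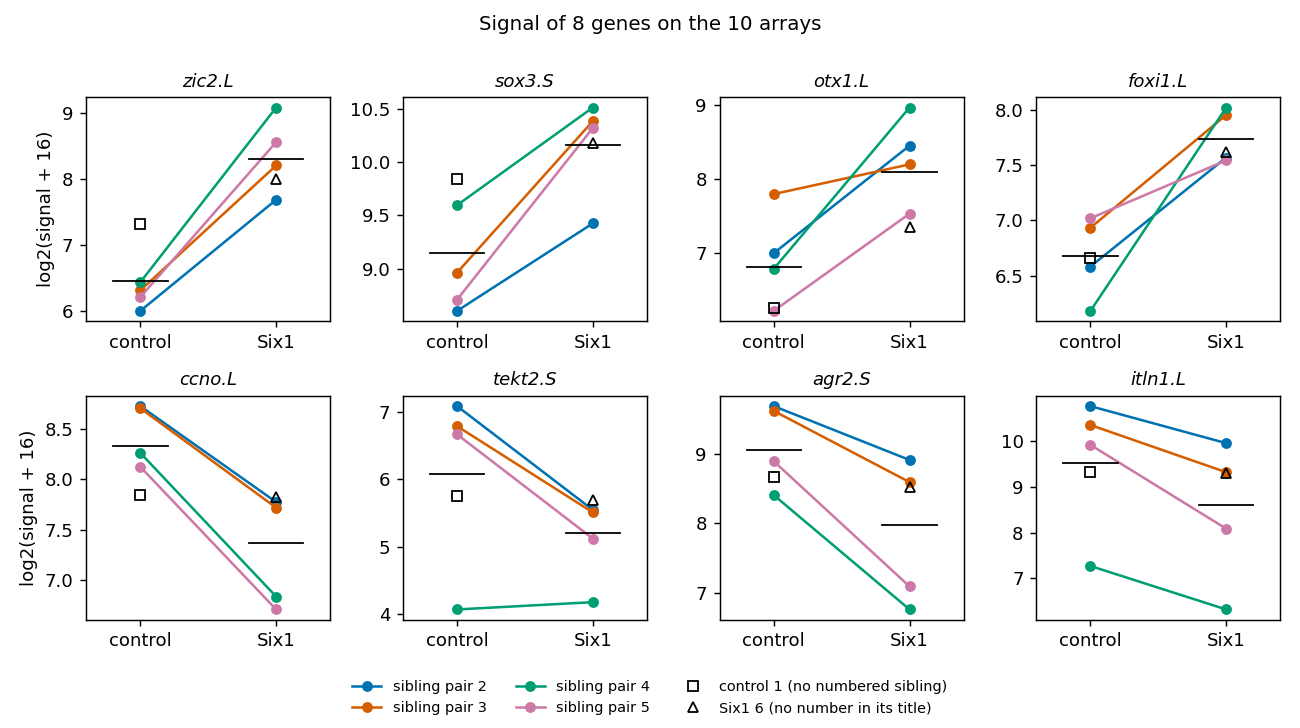
Signal of 8 genes on the 10 arrays as log2(signal + 16), with coloured lines joining the 4 sibling pairs, open symbols for the unpaired arrays and black bars for the mean of the 5 arrays of a group. zic2.L, sox3.S, otx1.L and foxi1.L were higher with Six1 in 4 of 4 pairs, ccno.L, agr2.S and itln1.L lower in 4 of 4, and tekt2.S lower in 3 of 4.

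Neural plate progenitor genes were shifted up as a group by camera with its preset correlation and by fry, though not with an estimated correlation. Of 27 measured members, 10 rose and 0 fell within the sibling pairs (13 and 2 when adjusted over the list alone), and the median log2 difference was 0.29 (0.27 on all arrays). Besides both zic2 copies, sox3.S, a SoxB1 factor of neural progenitors, rose 2.28-fold (log2 1.19, adjusted p = 0.0018), sox11.S by 1.14 on the log2 scale, zic1.S 2.05-fold and sox2.L 1.85-fold. The list also held foxd4l1.1.S (1.93-fold) and gmnn.L, geminin (1.64-fold), both of which keep neural ectoderm immature, and cdh2.L, N-cadherin (1.79-fold), and pou5f3.3.L (1.68-fold), which rose as well. A second probe set of sox2.L did not pass (log2 0.55, adjusted p = 0.090). The list median was 0.19 after median centring and 0.62 with the lower 50% of probe sets left out. The list was shifted up against the other genes by camera over the 22 lists (adjusted p = 4.1e-05 in pairs and 3.2e-05 on all arrays). With an estimated correlation the adjusted p = 0.23 in pairs and 0.10 on all arrays. Fry, which asks whether members move one way without comparing them with other genes, gave 0.024 and 0.018. It was not run after centring, so the higher medians of the Six1 arrays enter these values. The number of risen members was 7 (with 1 fallen) after quantile normalization and 8 (with 2 fallen) after median centring, where sox2.L, cdh2.L, pou5f3.3.L or gmnn.L dropped out, and 5 to 9 with a pair left out. With a pseudocount of 1 only 2 members rose.

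Among other regional markers the picture was mixed. In the preplacodal and otic placode list 3 of 12 members rose and 0 fell (7 and 3 adjusted over the list alone): otx1.L (2.52-fold, log2 1.33, SE 0.22), foxi1.L (2.13-fold) and irx1.L (1.83-fold). Without pair 3 only otx1.L passed, and with a pseudocount of 1 the count was 0. The list median was 0.57, but 0.35 with a pseudocount of 64 and 0.13 without the filter on dim probe sets, which 12 of 27 members pass. Camera did not call the list (adjusted p = 0.24 in pairs, 0.19 on all arrays, and 0.046 on all arrays without the filter on dim probe sets), while fry did (adjusted p = 0.0037 in pairs and 0.018 on all arrays). Hindbrain, spinal cord and posterior genes were shifted up (median 0.44, adjusted p = 0.0066 in pairs, 0.30 with an estimated correlation, 0.050 by fry, 0.069 on all arrays). The list median was 0.76 with a pseudocount of 1 and 0.18 with 64. Without the filter on dim probe sets it was 0.12 and the call was lost (adjusted p = 0.29). With the filter kept, cdx1.S (1.75-fold) and hoxa2.S (1.79-fold) rose in pairs among 8 members of the posterior list (4 and 0 adjusted over the list alone). Forebrain, midbrain and eye field genes had a median of 0.14 (adjusted p = 0.86) with 2 risen of 15, otx1.L and lhx5.S (1.56-fold), and 3 and 2 adjusted over the list alone. That median turned to -0.21 after quantile normalization and -0.15 with a pseudocount of 1, and was 0.04 after median centring. A second probe set of lhx5.S gave -0.25 (adjusted p = 0.45). Of 22 neural border and crest genes only prdm1.S, a transcriptional repressor of the neural plate border, passed (2.19-fold higher, lost without pair 3), with 6 and 2 adjusted over the list alone. Their median was 0.07 (adjusted p = 0.63), -0.03 after median centring and 0.19 without pair 4. None of 8 neuronal differentiation genes passed (0 and 2 adjusted over the list alone). Their median was -0.03 (adjusted p = 0.064), with -0.14 without pair 2 and 0.06 without pair 4, and tubb2b.S had the smallest p (log2 -0.56, adjusted p = 0.068). After quantile normalization the list was called lower (adjusted p = 0.027), and tubb2b.S passed under both scalings (0.048 and 0.041). The posterior gene hoxa2.S and lhx5.S lost their calls under both scalings.

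Genes of the ciliated epidermis were lower by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.30 in pairs and 0.35 on all arrays) or by fry (0.11 and 0.45). In the multiciliated cell and ionocyte list 4 of 23 members fell and 1 rose (8 and 2 adjusted over the list alone), with a median of -0.32. ccno.L and itln1.L fell as above, and the axonemal tektins tekt4.S and tekt2.S fell 1.75-fold and 2.09-fold. foxi1.L, which drives ionocyte formation, was the member that rose. Camera called the list lower (adjusted p = 3.6e-06 in pairs, 0.0048 on all arrays). Its members had an estimated correlation of 0.26 in pairs and 0.20 on all arrays, so these p-values with the preset 0.01 are too small. The call on all arrays was lost without control 3 (adjusted p = 0.075), without control 5 (0.062) and with the lower 50% of probe sets left out (0.20). Without pair 4 the median was -0.40 and 6 members fell. Without pair 2, 3 or 5 the count was 2, and without pair 5 the median was -0.20 (adjusted p = 2.8e-04). On all arrays it was -0.24, and -0.16 without control 5. Epidermis and keratin genes had a median of -0.18 (adjusted p = 0.0017 in pairs, 0.30 with an estimated correlation, 0.13 by fry, 0.064 on all arrays, and 0.087 in pairs after quantile normalization). That median was -0.28 after median centring or without pair 2. On all arrays it was -0.11, called with a variance trend (adjusted p = 0.042) and with array weights (0.016). Of 33 members, krt18.1.S and foxi1.L rose, and itln1.L and krt70.L (1.80-fold), an epidermal keratin, fell, the last not without pair 3 or 5 (4 and 3 adjusted over the list alone). The other copy of the keratin gene, krt18.1.L, differed by -0.46 (adjusted p = 0.20), and dlx3.S by -0.53 (0.10). Cement gland and hatching gland genes moved both ways: agr2.S and agr2.L (1.83-fold) fell, and ag1.L, a cement gland gene, rose 1.97-fold among 8 members (3 higher and 2 lower adjusted over the list alone). Their median was 0.05, while the mean was -0.06 and camera pointed down (adjusted p = 0.47). On all arrays the median was 0.24 and camera pointed up (0.81), and in pairs it was -0.15 with a pseudocount of 1. The call of ag1.L was lost under both scalings.

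Signalling lists also shifted by camera with its preset correlation, and none with an estimated one. BMP response genes were lower as a list of 32 members, with a median of -0.33 in pairs (adjusted p = 2.3e-04) and -0.22 on all arrays (adjusted p = 8.7e-05) and with adjusted p = 0.30 and 0.10 with an estimated correlation and 0.13 and 0.056 by fry. Without pair 5 the paired median was -0.18 (adjusted p = 0.014), and with a pseudocount of 64 it was -0.20. szl.L, the BMP-induced antagonist sizzled, fell 1.64-fold and bmp7.1.L, a BMP ligand, fell 1.59-fold. hes1.S (1.95-fold) and hes1.L (1.92-fold), bHLH-Orange repressors that act downstream of Notch as well, rose (4 higher and 9 lower adjusted over the list alone). The same hes1 pair and hes2.L (1.68-fold) rose in the Notch pathway list, where 3 of 14 members rose and 0 fell (6 and 0 adjusted over the list alone). Its median was 0.29 in pairs and 0.32 on all arrays, with an adjusted p = 7.5e-04 in pairs and 2.9e-04 on all arrays (0.23 and 0.10 with an estimated correlation, 0.0093 and 0.018 by fry). The paired median was 0.19 after median centring and 0.45 with the lower 50% of probe sets left out. hes1.L lost its call under both scalings and hes2.L under quantile normalization. Without pair 3, 0 members of either list passed. Wnt response genes had a median of 0.18 (adjusted p = 0.064) with sfrp2.S and cdx1.S risen of 15 (6 and 1 adjusted over the list alone). That list was called higher after quantile normalization (adjusted p = 0.033), after median centring (0.038, median 0.08), with array weights (0.0084, and 0.022 on all arrays) and without pair 4 (9.8e-04, median 0.27), though not by fry (0.11). Cell cycle genes were shifted up by a median of 0.18 over 60 members (adjusted p = 0.0066 in pairs, 0.033 on all arrays, 0.23 and 0.47 with an estimated correlation, 0.013 and 0.21 by fry). On all arrays the call was lost with a pseudocount of 1 and without control 2, 3 or 5, Six1 3 or Six1 4 (adjusted p 0.051 to 0.17). After median centring the median was 0.08 in pairs and 0.06 on all arrays. Of these, ccnb1.S, cyclin B1, rose 2.51-fold, rrm2.2.L, a ribonucleotide reductase subunit, 1.87-fold, mcm3.L, of the replicative helicase, 1.77-fold and cdc6.L, of origin licensing, 1.54-fold (6 and 0 adjusted over the list alone). rrm2.2.L and cdc6.L lost their calls after median centring. Without pair 4 only ccnb1.S passed, and without pair 3 or 5 the count was 2.

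Camera did not call the lists for other germ layers in the pairs, though some members changed and fry called the blood and the kidney list (adjusted p = 0.024 and 0.033). Endoderm genes had a median of -0.14 (adjusted p = 0.21, and 0.016 with the lower 50% of probe sets left out): the GATA factors gata6.L (2.15-fold) and gata5.S (1.72-fold) and a2m.S (1.78-fold) fell, and vegt.L, a maternal T-box factor, rose 2.43-fold, of 8 members (3 and 3 adjusted over the list alone). The median was -0.78 with the lower 50% left out, -0.33 without pair 5, -0.02 without pair 3 and -0.02 without the filter, and gata5.S and a2m.S lost their calls without pair 2 or 3. Of 9 blood and endothelium genes, aplnr.L (2.26-fold) and cebpa.S (1.99-fold) rose and cebpa.L, the other copy, fell 1.74-fold, with a median of 0.12, adjusted p = 0.57 and 2 and 1 adjusted over the list alone. That median was 0.02 under both scalings and -0.06 without pair 5, and without pair 3 only aplnr.L passed. Of 9 mesoderm and muscle genes, only myod1.S, a myogenic bHLH factor, passed (2.06-fold higher in 3 of 4 pairs, adjusted p = 0.048, lost under both scalings), with a median of 0.09 and an adjusted p = 0.93 (median 0.20 without pair 3, -0.03 without pair 5). On all arrays the median of that list was -0.03 and its mean 0.12. Notochord and organizer genes had a median of 0.28 (adjusted p = 0.68), with szl.L fallen of 6 members (3 and 1 adjusted over the list alone). Only 6 of 25 members pass the filter. Without it the median was 0.03 and camera pointed down (adjusted p = 0.71). Kidney and intermediate mesoderm genes had a median of 0.33 (adjusted p = 0.11, and 0.039 without pair 4), with irx1.L risen of 5 (2 and 0 adjusted over the list alone). Without the filter, which 5 of 14 members pass, that median was 0.06 (adjusted p = 0.71), and with array weights 0.50. For mesoderm, 1 and 0 passed when adjusted over the list alone.

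Genes reported as Six1 targets in other systems were shifted up by a median of 0.26 (adjusted p = 0.011 in pairs, 0.033 on all arrays, 0.30 and 0.22 with an estimated correlation, 0.040 and 0.054 by fry). The call was lost without the filter on dim probe sets (adjusted p = 0.063 in pairs, 0.065 on all arrays), with a pseudocount of 1 (0.054 and 0.051), and on all arrays without control 2, 3 or 5 or Six1 4 or 5 (0.060 to 0.089). The paired median was 0.14 after quantile normalization, 0.16 after median centring and 0.12 without the filter. foxi1.L and myod1.S rose among 15 members (6 and 0 adjusted over the list alone). The signal of myod1.S was low in controls (mean 13.7), and its call was lost under both scalings. Without pair 3, 0 members of the list passed. sesn1.L was the member that rose among 12 apoptosis and p53 genes (3 and 0 adjusted over the list alone), whose median was 0.07 (adjusted p = 0.47, and 0.029 by fry on all arrays), and -0.03 after median centring. hmox1.L, heme oxygenase, rose 2.17-fold among 20 heat shock and stress genes in 3 of 4 pairs (2 and 0 adjusted over the list alone). It lost its call after quantile normalization and without pair 3, 4 or 5. The list had a median of 0.06 (adjusted p = 0.85), -0.04 after median centring and 0.13 without pair 2. None of 70 ribosomal protein genes passed (0 and 0 adjusted over the list alone). Their median of -0.09 in pairs and -0.07 on all arrays was called (adjusted p = 2.3e-04 and 4.5e-04), and lost that call after quantile normalization (adjusted p = 0.087 and 0.14). With an estimated correlation (0.34 in pairs and 0.36 on all arrays) the adjusted p = 0.56 and 0.50, and fry gave 0.40 and 0.56. The paired median was -0.04 after quantile normalization, -0.19 after median centring, -0.15 with array weights, -0.02 without pair 3 and -0.16 without pair 4.

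**Figure D2:**
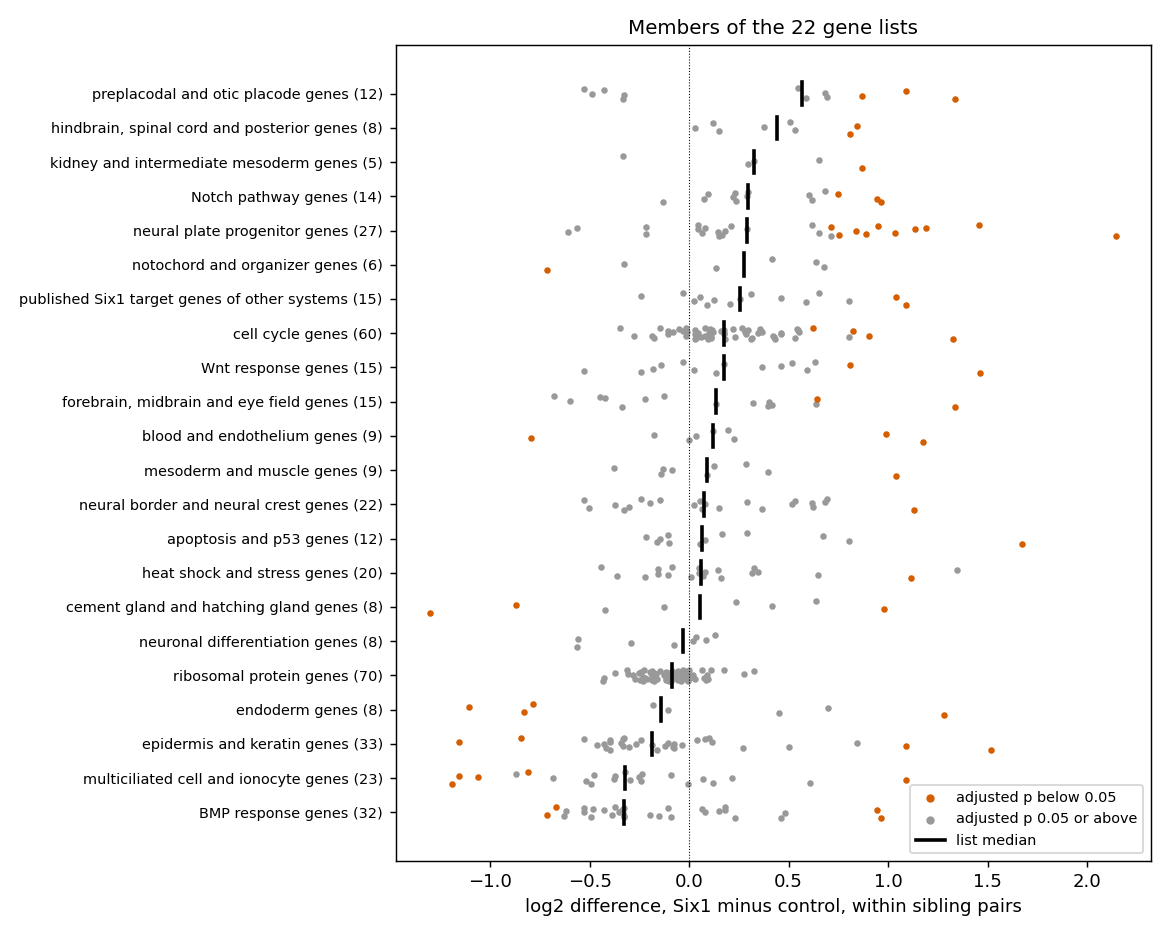
Log2 difference of Six1 minus control within the 4 sibling pairs for each measured member of the 22 gene lists, with the number of members in brackets, orange points for adjusted p below 0.05 and a black bar for the list median. The medians run from -0.33 for BMP response genes to 0.57 for preplacodal genes (0.13 without the filter on dim probe sets), and 10 neural plate progenitor genes are orange, each to the right of 0.

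Camera with its preset correlation called 7 of the 22 lists on all arrays and 9 in the pairs, and 0 with a correlation estimated from the residuals in either. That version has few degrees of freedom on so few arrays, so the 0 does not decide between correlated members and low power. In the pairs the estimated correlation was -0.05 for the Notch and -0.006 for the cell cycle list, below the preset 0.01. Both calls were lost all the same. For the other called lists it lay above 0.01: 0.34 for ribosomal protein, 0.26 for multiciliated, 0.13 for BMP response and 0.05 for epidermis genes. The neural plate, posterior and Six1 target lists had 0.02 to 0.03. Where members are correlated above the preset, its p-values are too small, most of all for the ribosomal and multiciliated lists. Fry called 4 on all arrays and 7 in the pairs, each of them higher. It was run only on values without further scaling, where the median of the Six1 arrays lay 0.09 higher on the log2 scale. Fry does not compare members with other genes, so that shift favours rises and works against falls. Many lists share genes: 10 of the 12 preplacodal members, 15 of the 32 BMP response members and 10 of the 15 Six1 target members stand in another list too. Of the 46 list members called in the sibling pairs, 4 (zic2.L, krt18.1.S, ccno.L and zic1.S) kept their calls under each alternative that tested them. With a pseudocount of 1 the number was 5, without pair 3 it was 19, without pair 4 29 and without pair 5 26.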

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

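The tests on scaling, on array medians, on dim probe sets and on the identity of the unnamed probe set with the largest difference were chosen after the results were seen. The others were written down before.

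12 of the 158 sample groups looked at had 1 sample far from the rest. The gap rule used is set to flag about 1 in 20 groups of independent normal values, and these groups share arrays. Control 1 was made from 97 explants, the other controls from 128 to 130. Control 4 had a beta-actin 3'/5' ratio of 5.104 (others 0.478 to 1.16) and a GAPDH 3'/5' ratio of 5.02 (others 2.01 to 2.65). Its log2 signal of krt18.1.S was 5.15 (others 6.05 to 6.40) and that of cdh2.L was 6.62 (others 5.93 to 6.01). tubb2b.S was at 8.57 in control 5 (others 7.48 to 7.67), and egr1.L was at 7.41 in control 1 (others 5.63 to 6.10). Among Six1 arrays, rab25.L was at 6.48 in Six1 6 (others 5.21 to 5.55) and cxcr4.S at 8.03 in Six1 5 (others 8.42 to 8.54). cebpa.L was at 5.35 in Six1 2 (others 6.998 to 7.32), rpl17.S at 8.84 in Six1 2 (others 8.61 to 8.67) and rpl4.S at 8.76 in Six1 4 (others 9.24 to 9.39). Among the probe sets left out as dim, hes7.1.L was higher with Six1 by 1.16 on the log2 scale (SE 0.19, limma adjusted p = 0.026 over the dim probe sets).

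Neural plate progenitor genes were higher with Six1 in the sibling pairs (median 0.29). Degraded RNA in control 4 would make this rest on pair 4, yet without that pair the median was 0.33 and the list kept its camera call with the preset correlation. Scaling between the arrays as the whole cause would remove the call under quantile normalization, but the adjusted p was 6.96e-06. Median centring lowered the list median to 0.19, while the list test compares members with the other genes and hardly sees such a shift. With an estimated correlation the list has no call (adjusted p = 0.23). A direct effect of Six1, an effect of the injection itself or a change in the makeup of the explants may underlie the shift, and none of these was tested.

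Multiciliated cell and ionocyte genes were lower (median -0.32). Without pair 4 the median was -0.40 (-0.20 without pair 5), and after quantile normalization the adjusted p was 3.99e-06, which argues against degraded RNA and against scaling as the whole cause, though with an estimated correlation the list has no call (adjusted p = 0.30). A candidate explanation is fewer cells with motile cilia in the Six1 explants. It predicted that further axoneme and ciliogenesis genes outside the fixed lists fall too. The 27 genes picked for this by symbol, which need not all be particular to motile cilia, had a median of -0.41, with 25 of 27 lower. Camera gave p = 4.88e-13 with its preset correlation and 0.061 with an estimated one. These genes were read on the same arrays as the list, so their fall is no independent support for this explanation. Lower expression per ciliated cell would give the same values and stays open.

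More probe sets were higher than lower in the sibling pairs. The array medians were higher in Six1 samples, and centring them left 30.3% of the calls higher. Centring moves this balance by its construction, so the value does not decide whether the medians are the cause. Over 3 equal groups of probe sets by signal, the median log2 difference was 0.10 in the dimmest, 0.10 in the middle and -0.01 in the brightest. The dimmest lay 0.11 above the brightest but not above the middle group, so a rise particular to dim probe sets is not decided by these values. RNA input, hybridization background and a true rise of weakly expressed genes stay open and were not tested.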

How the results depend on the processing

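The sibling pairs' own alternatives were chosen after seeing the data, the others before. Across all 10 arrays 4 probe sets were higher and 1 lower. With the sibling pair as a block the counts were 221 and 159, and with the pair as a random block 64 and 36. A pseudocount of 1 gave 1 and 0, and quantile normalization, a pseudocount of 64 and 1 probe set per named gene each gave 0 lower. Leaving out 1 array at a time gave 1 to 10 higher and 0 to 1 lower. The count of higher was 10 without control 1, 2 without control 4 or Six1 3, and 1 without control 2, control 5, Six1 5 or Six1 6. In the paired fit the higher and lower counts were 111 and 172 after quantile normalization, 104 and 239 after median centring, 15 and 12 with a pseudocount of 1, 129 and 132 with 64, 129 and 100 without the filter on dim probe sets, and 662 and 443 with array weights. Leaving out 1 pair gave 52 to 178 higher (52 without pair 3, 84 without pair 5, 97 without pair 4) and 35 to 118 lower (35 without pair 3, 60 without pair 5). With fewer arrays the test has fewer degrees of freedom; for the other settings the cause was not tested. Of the 380 paired calls, 255 were kept after quantile normalization, 263 after centring, 27 with a pseudocount of 1 and 87 without pair 3. All calls tested under these settings kept their sign, which is no independent check, since the settings share arrays.

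Among gene lists, the neural plate, multiciliated, BMP response, Notch and cell cycle calls of the paired fit were kept in 13 of 13 settings with the preset correlation, of which median centring hardly bears on this test, and lost with an estimated correlation (adjusted p 0.23 to 0.30). Fry did not call the multiciliated and BMP response lists, but it was run without centring, where the higher Six1 medians work against a fall. The random block was not run for lists, since camera takes none. Over the 74 named genes and their settings, 1416 values on all arrays stayed on their side of the threshold in the same direction, 37 lost a call and 92 gained one, most of these with the pair as a block. In the paired fit the numbers were 688, 175 and 15, and 1 gene without a call changed sign. No result reversed its direction past the threshold under any alternative run. Signal over background limits the values of dim genes, and no detection calls were at hand. A pseudocount of 1, which gives noise at low signal more weight, left the fewest calls in the paired fit. Bright genes lost calls there too, such as sfrp2.S (mean signal 1244 in controls and 2810 in Six1 samples). The loss was thus not limited to dim genes.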

Other observations

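The test on cilia genes was written down before its result was seen, as were the tests on other splits of the samples. Values of the cilia genes dnali1.S and dydc1.L had already been seen, and both were left out of the cilia test. The test on the unnamed probe set was chosen after.

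Outside the fixed lists, 25 of the 27 further genes picked by cilia-related symbols were on the lower side with Six1 in the sibling pairs. The pick by symbol does not show that each belongs to motile cilia. spata6l.L fell by 0.89 on the log2 scale (limma adjusted p = 0.0062), rsph1.L, a radial spoke head protein, by 0.86 (0.0077) and meig1.S by 0.79 (0.015). The other 24 did not pass, among them dnai4.S (-0.61, adjusted p = 0.051) and ak7.S (-0.78, 0.063), and 2 were on the higher side, dnaaf5.L (0.20) and spag7.L (0.02).

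The probe set without a gene name that was far higher on the Six1 arrays may measure the injected Six1 mRNA, which these values do not decide. It was picked for its separation, so it says nothing about its identity that 0 other tested probe sets had each Six1 array at least 10-fold above each control array on the scale of signal + 16. On that scale its lowest Six1 value lay 48.7-fold above the highest control value, against 1.65-fold for aplnr.L, the next. A gene that is silent in control caps and induced by Six1 would look the same, and the sequence of the probe set was not used here.

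Other splits of the 10 arrays into 5 and 5 gave as many probe sets as the real 5 in 4 of 100 splits drawn, the real one included, and the highest other split gave 27. That share is under 0.05, but it comes from splits that ignore the sibling pairs. The 12 other splits drawn that part all 4 pairs gave at most 0, and they are too few for a share under 0.05. The 27 calls came from the 87 splits drawn that part fewer pairs. They point to some structure of the samples, in which the likeness of siblings may enter, and this was not tested. Swapping labels within the 4 pairs allows 8 arrangements, too few for a share under 0.05: the real one gave 380 and the highest other 0, and 1 of 8 reached the real count.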
